A study of Schizosaccharomyces pombe with 15 samples.

How the data were processed

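RNA was sequenced from fission yeast strain JY450, wild type, without irradiation, 10, 15 and 30 min after irradiation with atmospheric-pressure plasma, and after H2O2. Per the labels' protocols, cells grew in YE medium, cells in logarithmic or stationary phase were placed on a membrane filter on agar and irradiated, RNA was extracted with hot phenol, and libraries were made with a stranded mRNA kit. The labels give 10, 15 and 30 min as time points, and the series text places them after irradiation. The growth phase of these samples, the plasma dose, and the dose and time of H2O2 are not given in the sources used here. Per the submitters' processing notes, reads were aligned with HISAT2 2.2.1 and handled with SAMtools 1.13 on a build named R64. Per the file headers, featureCounts 2.0.1 summed read pairs over transcript features by gene identifier, and its command line set no strand option.

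The authors deposited raw counts in 2 tables of 6998 genes each, 1 with the 12 plasma and control libraries and 1 with the 3 H2O2 libraries. The values were checked to be whole numbers, and 965 genes had 0 counts in all 15 libraries. Identifiers and chromosomes in the tables are those of fission yeast, although R64 is a name used for budding yeast, so coordinates are given as the deposited tables list them and no build is stated. A reference annotation was used for names alone, in which 6852 identifiers were matched and 4422 had a symbol of their own. The H2O2 table had no control columns, so both tables were joined on the identifier and H2O2 was compared with the same 3 control libraries. Column names carry the letters a to c rather than the replicate numbers of the labels, so libraries are named by group and letter. No column of values was left out.

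Genes were kept with filterByExpr by group, which left 5214, and scaled with TMM. All 15 libraries were fitted in 1 model with a mean per group in edgeR 4.0.16 (glmQLFit and the two-sided quasi-likelihood F-test), run in R 4.3.3, with a common biological coefficient of variation of 8.8%. The 10 comparisons were each treatment with no irradiation, the 3 pairs of plasma times, and each plasma time with H2O2, which equals the difference of the changes from the shared controls. The p-values were adjusted per comparison with the Benjamini-Hochberg method at 0.05. They measure the spread between these samples, which the labels call biological replicates. CPM used the TMM-scaled library sizes. Library totals were 14691752 to 23232575 counts. Between replicate pairs the chi-square per degree of freedom was 9.02 to 81.83, where counting error alone gives about 1. Summed over genes, the spread between libraries thus exceeded counting error, which need not hold for weakly expressed genes.

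Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation between genes of 0.01 and, as an alternative, an estimated one, adjusted over the 26 lists of a comparison. The lists covered antioxidant enzymes, Pap1-regulated genes, the core environmental stress response, heat shock and chaperones, the unfolded protein response, the proteasome, sulfur and glutathione metabolism, iron uptake, NADPH supply, glycolysis, alternative carbon use, nuclear oxidative phosphorylation, cytoplasmic ribosomal proteins, ribosome biogenesis, DNA damage repair, MBF targets, histones, mitosis and cell separation, nitrogen starvation and mating, phosphate and thiamine regulation, ergosterol and hypoxia, autophagy, stress kinase signalling, mitochondrially encoded genes, Tf2 retrotransposons and non-coding RNA genes. They were written from textbook knowledge, and 24 names matched no gene. Members can stand in several lists: 7 of the 19 matched Pap1 genes, 11 of the 40 core stress genes and 8 of the 24 antioxidant genes also stood in another list. Some members were matched by name alone, such as rpp21 and rps3, and the lists were also tested without them.

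Comparisons, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule named, for each treatment against no irradiation, the 8 highest and the 8 lowest log2 fold changes among genes with adjusted p under 0.05, a mean count of at least 50, no overlap of treated and control libraries, and no membership in the non-coding, Tf2 or mitochondrial lists. It also named the 3 members with the smallest p in each list that passed, a panel of 20 stress genes of which 19 were tested, and the 5 highest and 5 lowest genes of each other comparison. Of the 126 genes so named, 61 overlap another annotated gene and 11 over at least 50% of their length, and reads from either strand in such stretches cannot be assigned with certainty.

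Alternatives were RLE size factors, total counts without TMM, DESeq2 1.42.0, no filter on low counts, a filter of at least 1 CPM in at least 3 libraries, a fit to the groups compared alone, a 2-fold minimum, no non-coding, Tf2 and mitochondrial genes, and each library left out in turn. Library letter as a block was added after the data were seen, and lists without members matched by name alone were added after the names were matched and before any test. The overlap of calls was set beside 20 simulated data sets of unchanged groups. The workflow was tested on simulated data, in which genes changed 2-fold were recovered in 83.6 to 97% of cases and those changed 1.5-fold in 76.1 to 83.6%, with 5 to 14 false calls among 178 to 194, and camera called 10 of 10 shifted and 0 of 40 unshifted sets. These simulations changed 66 or 67 genes at each fold, far fewer than were called in the data. Their genes varied independently, so they could not show false list calls from genes that vary together. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.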

Results

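RNA sequencing counts were analysed for 15 libraries of a wild-type fission yeast strain, JY450, in 5 groups of 3 biological replicates. The groups were cells without irradiation and cells 10, 15 and 30 min after irradiation with atmospheric-pressure plasma (an ionised gas that generates reactive oxygen and nitrogen species). The fifth group was treated with hydrogen peroxide (H2O2). Library totals ran from 14691752 to 23232575 counts. Of the 6998 genes listed, 5214 had enough counts to be tested. Values per gene are mean CPM (counts scaled to a common library size) ± SD with n = 3 per group, and log2 fold changes are given ± SE.

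The first principal component held 45.6% of the variance and placed the 3 libraries without irradiation between -34.59 and -30.14, while the 12 treated libraries lay between -2.44 and 17.07. At each later plasma time more genes differed from no irradiation. The 3 times share the same control group, whose labels give no time, so plasma and time after handling cannot be told apart. The genes higher than without irradiation numbered 1141 at 10 min, 1412 at 15 min and 1616 at 30 min, and the genes lower numbered 884, 1295 and 1510. Fitted to the groups compared alone, 546 genes were lower at 10 min. H2O2 raised 1486 genes and lowered 1336. With total counts in place of TMM scaling the balance turned, to 1223 higher and 1619 lower at 30 min and 1255 and 1266 with H2O2. Changes of at least 2-fold were mainly increases. They numbered 240 genes higher and 35 lower at 10 min, 306 and 82 at 15 min, 356 and 111 at 30 min, and 343 and 65 with H2O2. All 3 treated libraries lay outside the range of the 3 controls for 43.7%, 56, 62.2 and 58.8% of genes in these comparisons, where chance gives 10%.

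**Figure D1:**
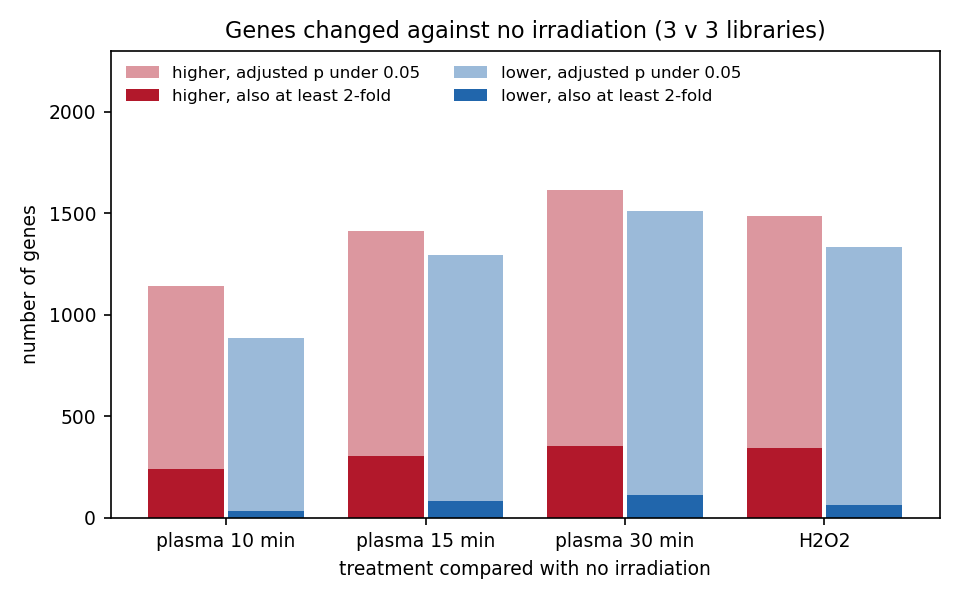
Number of genes (vertical axis) higher (red) or lower (blue) than without irradiation at adjusted p under 0.05, with the part changed at least 2-fold in full colour, for each treatment (horizontal axis, 3 libraries against 3). At 30 min after plasma 1616 genes were higher and 1510 lower, of which 356 and 111 changed at least 2-fold.

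The comparison at 10 min after plasma asked which transcripts had responded first. srx1 (SPBC106.02c, chromosome II, 376253 to 377036), which encodes sulfiredoxin, the enzyme that repairs over-oxidised peroxiredoxin, rose from 17.98 ± 0.775 to 390 ± 43.1 CPM (log2 fold change 4.44 ± 0.09, adjusted p = 3.91e-14). ctt1 (SPCC757.07c, chromosome III, 56654 to 58865), the catalase gene, rose from 250 ± 70.7 to 2960 ± 447 CPM (3.56 ± 0.17, adjusted p = 1.75e-09). The largest increase was that of wwm3 (SPBC660.05, chromosome II, 202257 to 203623), a stress-induced gene, from 7.57 ± 2.16 to 449 ± 24.2 CPM (58.5-fold, adjusted p = 1.21e-09). pyp2 (SPAC19D5.01, chromosome I, 5202366 to 5205202), which encodes a phosphatase that switches off the stress-activated kinase Sty1, rose 24.8-fold, from 13.1 ± 1.75 to 323 ± 30.4 CPM. The largest decreases were in the neighbouring uracil-regulated genes urg1 (SPAC1002.19, chromosome I, 1835270 to 1837060), from 584 ± 161 to 56.9 ± 14 CPM (-3.36 ± 0.2, adjusted p = 5.95e-09), and urg2 (SPAC1002.17c), from 509 ± 90.1 to 73.8 ± 17.5 CPM. The iron uptake genes fip1 (SPAC1F7.07c), an iron permease, and fio1 (SPAC1F7.08), its partner oxidase, fell from 105 ± 11.3 to 36.1 ± 4.06 CPM and from 69.1 ± 4.85 to 24.6 ± 3.27 CPM. Of the 20 genes of the iron uptake list 4 rose and 5 fell (4 and 5 adjusted over the list alone), and the list did not pass (adjusted p = 0.353, and 0.732 with an estimated correlation).

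Among the gene lists at 10 min, 34 of the 37 measured core environmental stress genes rose and 3 did not pass the test (35 rose adjusted over the list alone). Their median log2 fold change was 1.76 (adjusted p = 3.25e-20). Examples were the trehalose synthase gene tps1, at 1620 ± 265 against 511 ± 254 CPM, and the glutathione peroxidase gene gpx1, at 753 ± 122 against 289 ± 94.4 CPM. Of the 16 genes regulated by Pap1, the transcription factor activated by peroxide, 13 rose (14 adjusted over the list alone, adjusted p = 1.4e-07), among them gst3, a glutathione transferase, by 1.84 ± 0.13. The thioredoxin reductase gene trr1 did not pass, at 351 ± 59.0 against 269 ± 9.27 CPM (log2 fold change 0.39, adjusted p = 0.0714). Without library a of plasma 10 min it passed, with a log2 fold change of 0.52. Of 30 autophagy genes 24 rose (24 adjusted over the list alone, adjusted p = 6.44e-08), including atg4 by 1.45 ± 0.12. Of 28 stress kinase pathway genes 15 rose and 1 fell (15 and 2 adjusted over the list alone, adjusted p = 5.93e-04), including the kinase gene srk1 by 2.47 ± 0.14. Antioxidant enzyme genes as a list did not pass at 10 min, with 9 of 24 higher and 1 lower (10 and 1 adjusted over the list alone, adjusted p = 0.0694). Without library b of the controls that list passed (0.00903), as it did without library a (0.0413) or c (0.0495) of plasma 10 min. Ribosome biogenesis genes moved down, with 61 of 93 lower and 1 higher (71 and 1 adjusted over the list alone, adjusted p = 1.7e-15), such as imp4 by -0.8 ± 0.09. Of 25 genes of mitosis and cell separation 13 fell and 3 rose (13 and 4 adjusted over the list alone, adjusted p = 0.0195), with slp1, which activates the ligase that ends mitosis, at 190 ± 25.1 against 390 ± 25.6 CPM. Of 15 ergosterol and hypoxia genes 6 fell (7 adjusted over the list alone, adjusted p = 0.00797), such as erg31 by -0.49 ± 0.08. The 117 cytoplasmic ribosomal protein genes shifted by a median of -0.20 (adjusted p = 5.76e-07), although only 4 of them fell in the test per gene (2 adjusted over the list alone), among them rpp21, which encodes an RNase subunit rather than a ribosomal protein. These list calls did not hold with an estimated correlation. The adjusted p was then 0.204 for the core stress, Pap1 and autophagy lists and 0.493 for the stress kinase list. It was 0.438 for ribosome biogenesis and ergosterol, 0.732 for mitosis and 0.767 for ribosomal proteins.

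Heat shock genes also moved up at 10 min, with 12 of 25 higher and 1 lower (14 and 1 adjusted over the list alone, adjusted p = 0.0204, and adjusted p = 0.732 with an estimated correlation). hsp16, a small heat shock protein, stood at 304 ± 97.1 against 89.9 ± 52.1 CPM (adjusted p = 7.9e-04), and hsf1, the heat shock transcription factor, rose by 0.63 ± 0.07. hsp104, a disaggregase, stood at 858 ± 176 against 377 ± 312 CPM (adjusted p = 0.0268). The wide control SD came from library b without irradiation, which held 737 CPM of hsp104 where libraries a and c held 209 and 185. With 1 library of either group left out, the adjusted p of the list in camera ran from 7.85e-05 to 0.103. The list call was lost without library a (adjusted p = 0.0642) or c (0.103) without irradiation, or without library b (0.0533) or c (0.0593) of plasma 10 min. The call for hsp104 was lost without those 2 control libraries (log2 fold change 0.9 and 0.86) or library b of plasma 10 min (0.99), and its log2 fold change was 2.11 without library b of the controls.

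At 15 min the same question was asked of a later sample. srx1 reached 793 ± 29.1 CPM (log2 fold change 5.46 ± 0.1, adjusted p = 3.4e-15) and ctt1 5190 ± 312 CPM (4.37 ± 0.18, adjusted p = 1.5e-10), while urg1 stood at 22.2 ± 2.48 CPM (-4.71 ± 0.21, adjusted p = 2.18e-10). The strongest cell cycle change was in slp1 (SPAC821.08c, chromosome I, 994941 to 997625), which fell from 390 ± 25.6 to 80.2 ± 12.3 CPM (-2.28 ± 0.11, adjusted p = 5.62e-10). trr1 now passed, at 794 ± 231 CPM (1.56 ± 0.17, adjusted p = 1.52e-06), although 70.3% of its interval overlaps a non-coding gene and counting had no strand option. Library a of plasma 15 min held 1057 CPM of trr1, where libraries b and c held 620.4 and 704.4. On the second principal component that library lay at -2.89 and the other 2 at -12.95 and -13.14. lsd90 (SPBC16E9.16c), a stress-induced gene, stood at 2670 ± 412 against 63.4 ± 48.0 CPM (5.4 ± 0.45), and its log2 fold change was 6.23 without library b of the controls. mmf2 (SPAC1039.10), linked to isoleucine synthesis, fell from 45.5 ± 4.72 to 7.24 ± 0.512 CPM.

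At 15 min, 35 of the 37 core stress genes rose (35 adjusted over the list alone, adjusted p = 4.21e-17), with a median of 2.08. Of the 16 Pap1-regulated genes 15 rose (15 adjusted over the list alone, where 1 also fell, adjusted p = 2.57e-09), with a median of 1.56. caf5, a spermine family transporter, stood at 174 ± 43.3 against 28.8 ± 0.491 CPM. Antioxidant enzymes moved up, 11 of 24 higher and 3 lower (11 and 3 adjusted over the list alone, adjusted p = 0.0153). Autophagy genes rose in 25 of 30 cases (26 adjusted over the list alone, adjusted p = 1.92e-07). Stress kinase genes rose in 18 of 28, with 1 lower (18 and 2 adjusted over the list alone, adjusted p = 6.74e-05). Mitosis and cell separation genes fell in 19 of 25 cases, with 2 higher (21 and 2 adjusted over the list alone, median -0.67, adjusted p = 4.05e-08), including cdc15, a protein of the contractile ring, by -1.26 ± 0.07. Ribosome biogenesis genes fell in 79 of 93 cases, with 2 higher (79 and 2 adjusted over the list alone, adjusted p = 1.18e-15). Of 117 ribosomal protein genes 55 fell, with 1 higher (11 lower adjusted over the list alone, adjusted p = 4.58e-08). DNA damage repair genes moved up, 17 of 33 higher and 4 lower (17 and 4 adjusted over the list alone, adjusted p = 0.0407), among them the endonuclease gene uve1 by 0.99 ± 0.07. Genes of the G1/S programme controlled by the factor MBF moved down, 9 of 18 lower and 4 higher (9 and 4 adjusted over the list alone, adjusted p = 0.049), among them cdt1 by -1.33 ± 0.09 and mik1 by -1.4 ± 0.1. The DNA repair call was lost without library a of plasma 15 min (adjusted p = 0.0612), and the MBF call without library b of the controls (0.0881) or library a of plasma 15 min (0.0709). The MBF call was also lost with the library letter as a block. At 15 min the adjusted p with an estimated correlation was 0.157 for the Pap1, autophagy and DNA repair lists, 0.227 for core stress and 0.253 for mitosis. It was 0.387 for the stress kinase and ribosome biogenesis lists, 0.615 for antioxidants, 0.656 for MBF and 0.693 for ribosomal proteins.

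Mitochondrially encoded transcripts were also lower at 15 min, with 7 of the 8 listed genes lower (7 adjusted over the list alone, median -1.95, adjusted p = 0.049, and adjusted p = 0.656 with an estimated correlation). At 10 min the list did not pass (median -1.05, adjusted p = 0.208), but it did with the library letter as a block (adjusted p = 0.013), so a fall by 10 min is not excluded. The other listed gene, rps3, is a nuclear gene of the cytoplasmic ribosome matched by its name. The ribosomal RNA genes, a residue in libraries made from polyadenylated RNA, made up 0.155 ± 0.153% of the counts at 15 min, against 0.7 ± 0.419% without irradiation, 0.249 ± 0.0881% at 10 min, 0.662 ± 0.408% at 30 min and 0.656 ± 0.558% with H2O2. The share of mitochondrial genes was 0.0045 ± 0.00401% at 15 min and 0.0159 ± 0.0098% without irradiation. Library a had the highest and library c the lowest of both shares in each of the 5 groups. The list call was lost without control library a (adjusted p = 0.0942) or b (0.0881), or without library b (0.0701) or c (0.101) of plasma 15 min.

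**Figure D2:**
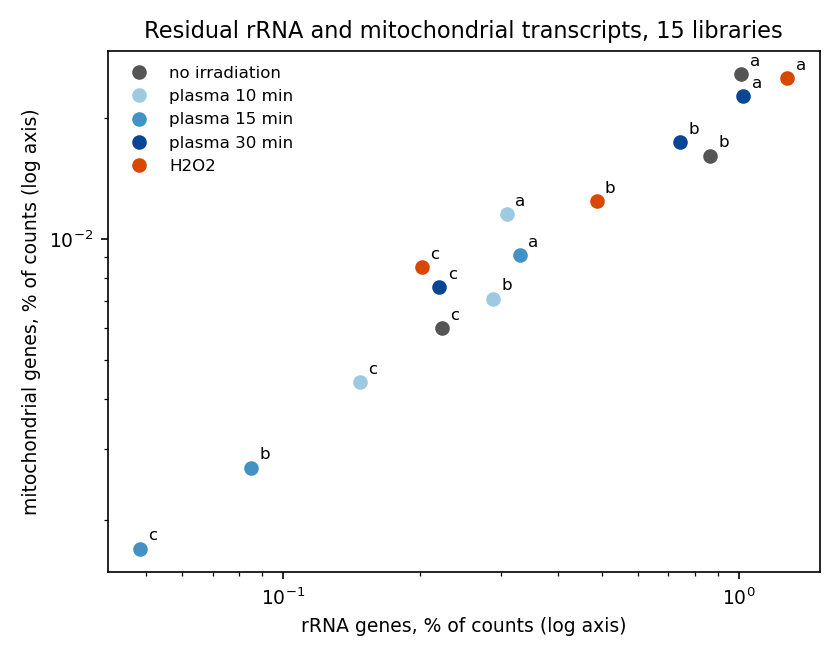
Share of counts from mitochondrial genes (vertical log axis, %) against the share from ribosomal RNA genes (horizontal log axis, %) in each of the 15 libraries (points, coloured by group, with the library letter). The 3 libraries of plasma 15 min had a mean ribosomal RNA share of 0.155% and those without irradiation 0.7%.

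At 30 min after plasma, ctt1 reached 7490 ± 842 CPM (log2 fold change 4.9 ± 0.19, adjusted p = 2.72e-11) and srx1 stood at 744 ± 40.8 CPM (5.37 ± 0.09). The dehydrogenase gene SPAC22A12.17c (chromosome I, 1185837 to 1189506) rose from 13.1 ± 1.47 to 419 ± 78.3 CPM (4.99 ± 0.18, adjusted p = 1.8e-11). zym1 (SPAC22H10.13), which encodes a metallothionein that binds zinc, rose 9.82-fold, from 33.2 ± 6.18 to 327 ± 29.4 CPM, and gst2, a glutathione transferase, rose from 394 ± 38.4 to 2080 ± 82.0 CPM. Among the lowest were slp1, at 82.1 ± 7.98 CPM (-2.25 ± 0.11) and urg1, at 115 ± 8.56 CPM (-2.34 ± 0.19). ste11 (SPBC32C12.02), the master regulator of sexual differentiation, fell from 19.96 ± 1.58 to 8.97 ± 0.635 CPM (-1.15 ± 0.1). At 10 and 15 min ste11 had been higher by 0.25 ± 0.09 and 0.28 ± 0.09, calls lost without any of 5 and any of 3 single libraries. pho84, a phosphate transporter gene, stood at 6.5 ± 1.84 against 23.8 ± 5.91 CPM, but 89% of its interval is shared with the non-coding gene prt2, so the transcript behind this value is uncertain.

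At 30 min core stress genes rose in 36 of 37 cases (36 adjusted over the list alone, median 2.44, adjusted p = 1.48e-16). Pap1-regulated genes rose in 15 of 16 (15 adjusted over the list alone, median 2.10, adjusted p = 1.1e-09) and antioxidant enzymes in 16 of 24 (16 adjusted over the list alone, adjusted p = 6.42e-05). Proteasome genes rose in 28 of 34 cases (28 adjusted over the list alone, median 0.24, adjusted p = 1.09e-04), for example pre9 by 0.7 ± 0.06. Of 20 iron uptake genes 11 rose and 4 fell (12 and 4 adjusted over the list alone, adjusted p = 0.0231). The ferrichrome synthesis gene sib2 rose by 2.01 ± 0.08 and the siderophore transporter gene str1 by 1.38 ± 0.09, and the list also held srx1, which encodes no iron transporter. Autophagy genes rose in 25 of 30 cases (25 adjusted over the list alone, adjusted p = 1.06e-07) and stress kinase pathway genes in 20 of 28 (20 adjusted over the list alone, adjusted p = 1.49e-05). Ribosomal protein genes fell in 114 of 117 cases, with 1 higher (114 and 1 adjusted over the list alone, median -0.47, adjusted p = 3.44e-13), such as rps2202 by -1.05 ± 0.07. Ribosome biogenesis genes fell in 82 of 93, with 2 higher (82 and 2 adjusted over the list alone, adjusted p = 9.38e-19), such as nop2 by -1.02 ± 0.07, a gene with 60% of its interval shared with another. Mitosis and cell separation genes fell in 18 of 25, with 2 higher (18 and 2 adjusted over the list alone, median -0.70, adjusted p = 8.56e-07). None of these calls held with an estimated correlation. The adjusted p was then 0.202 for the core stress, Pap1, iron and autophagy lists, 0.26 for the antioxidant, stress kinase, ribosome biogenesis and mitosis lists, and 0.58 for the proteasome and ribosomal proteins.

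The H2O2 comparison asked how cells answered a single oxidant. srx1 rose from 17.98 ± 0.775 to 1590 ± 64 CPM (88.1-fold, log2 fold change 6.46 ± 0.1, adjusted p = 5.29e-16). ctt1 rose to 9720 ± 141 CPM (5.28 ± 0.19, adjusted p = 1.24e-11) and trr1 to 2750 ± 163 CPM (3.36 ± 0.18, adjusted p = 6.34e-10). Pap1 targets were among the strongest, with caf5 (SPBC609.04) at 1040 ± 32.4 CPM (5.17 ± 0.16), a gene with 41.3% of its interval shared with a non-coding gene, and the dehydrogenase gene osr1 (SPCC663.06c, chromosome III, 1644754 to 1645876) at 594 ± 63.2 against 19.5 ± 1.29 CPM (4.92 ± 0.16, adjusted p = 6.65e-12). adh8 (SPBC1773.06c), an alcohol dehydrogenase, rose from 44.1 ± 1.39 to 889 ± 83.8 CPM. Among the lowest were slp1, at 127 ± 2.59 CPM (-1.61 ± 0.11), and agn1 (SPAC14C4.09), a glucanase that separates daughter cells, at 108 ± 11.2 against 293 ± 11.3 CPM (-1.44 ± 0.09, adjusted p = 3.34e-09). The heat shock genes hsp104, at 345 ± 22.4 against 377 ± 312 CPM (adjusted p = 0.799), and hsp16, with a log2 fold change of 0.68 ± 0.34 (adjusted p = 0.101), did not pass. Without library b of the controls both passed, hsp104 with a log2 fold change of 0.81 and hsp16 with 1.27.

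With H2O2, 15 of 16 Pap1-regulated genes rose (15 adjusted over the list alone, median 2.52, adjusted p = 5.95e-12). So did 34 of 37 core stress genes (34 adjusted over the list alone, median 1.78, adjusted p = 5.26e-15). Of 24 antioxidant enzyme genes 15 rose and 3 fell (15 and 3 adjusted over the list alone, adjusted p = 7.31e-05). Of 30 autophagy genes 24 rose and 1 fell (24 and 1 adjusted over the list alone, adjusted p = 2.65e-07), and of 28 stress kinase pathway genes 20 rose (20 adjusted over the list alone, adjusted p = 9.43e-07). Genes of alternative carbon use rose in 13 of 16 cases, with 1 lower (14 and 1 adjusted over the list alone, median 0.94, adjusted p = 1.82e-05), including the hexose transporter gene ght7 by 1.79 ± 0.15. After plasma that list did not pass at 15 min (median 0.449, adjusted p = 0.0681) or 30 min (median 0.454, adjusted p = 0.0502), but it passed at both without library c of the controls (0.0469 and 0.0274) and at 30 min without library a of plasma 30 min (0.0282). DNA damage repair genes moved up, 15 of 33 higher and 2 lower (15 and 2 adjusted over the list alone, adjusted p = 0.03), with uve1 higher by 0.77 ± 0.07. Nuclear genes of oxidative phosphorylation moved down, 19 of 41 lower and 4 higher (19 and 4 adjusted over the list alone, adjusted p = 0.0165), such as cox5 by -0.44 ± 0.06. Ribosome biogenesis genes fell in 78 of 93 cases, with 5 higher (80 and 5 adjusted over the list alone, adjusted p = 8.99e-16). Ribosomal protein genes fell in 87 of 117 (102 adjusted over the list alone, adjusted p = 1.58e-10) and mitosis and cell separation genes in 17 of 25, with 2 higher (18 and 2 adjusted over the list alone, adjusted p = 2.98e-06). For H2O2 the adjusted p with an estimated correlation was 0.122 for the Pap1, alternative carbon, DNA repair and autophagy lists, 0.234 for the core stress, antioxidant, stress kinase, ribosome biogenesis and mitosis lists. It was 0.63 for oxidative phosphorylation and ribosomal proteins. The H2O2 libraries stood in a separate table with no control columns of its own, so table and treatment cannot be told apart.

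**Figure D3:**
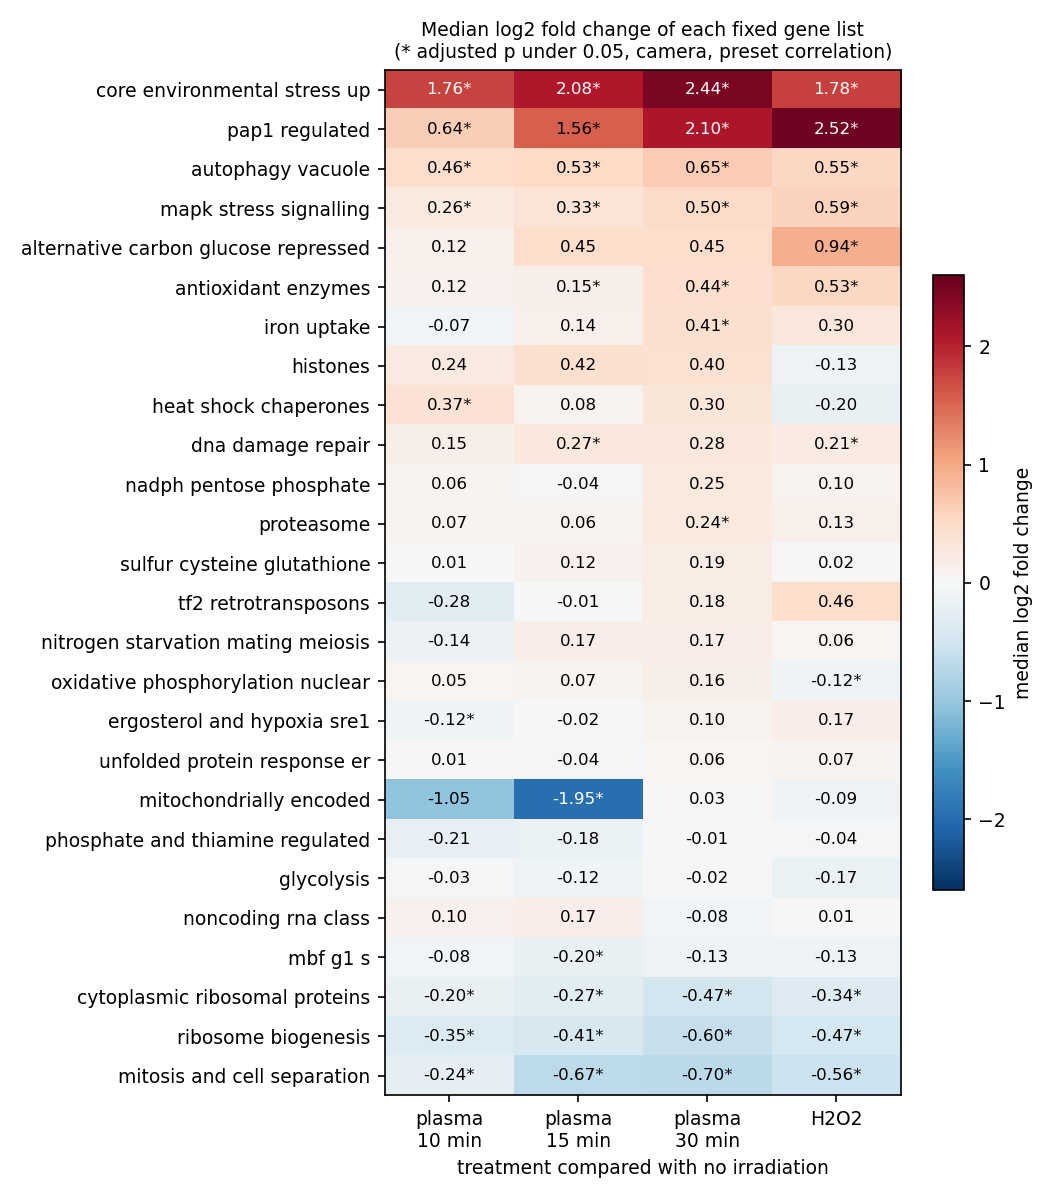
Median log2 fold change (colour and printed value) of each of the 26 gene lists (vertical) for each treatment against no irradiation (horizontal), with a star where the list test passed with the preset correlation. The core stress list stood at 1.76, 2.08 and 2.44 at 10, 15 and 30 min after plasma and at 1.78 with H2O2, and the Pap1 list at 0.64, 1.56, 2.10 and 2.52, while medians between -0.005 and 0.059 can change sign with the scaling.

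The remaining lists passed in none of these 4 comparisons. In the order 10, 15 and 30 min after plasma and H2O2, the adjusted p was 0.976, 0.546, 0.658 and 0.541 for the unfolded protein response. It was 0.549, 0.289, 0.51 and 0.723 for sulfur and glutathione metabolism, and 0.708, 0.962, 0.11 and 0.192 for NADPH supply. It was 0.779, 0.45, 0.86 and 0.541 for glycolysis and 0.304, 0.118, 0.0596 and 0.295 for histones. It was 0.402, 0.402, 0.586 and 0.458 for nitrogen starvation and mating, and 0.208, 0.18, 0.262 and 0.194 for phosphate and thiamine regulation. For Tf2 retrotransposons it was 0.222, 0.884, 0.51 and 0.117, and for the 636 non-coding RNA genes 0.195, 0.113, 0.586 and 0.92. Median and mean differed in sign for glycolysis in these 4 comparisons, for sulfur at 10 min, for the unfolded protein response and NADPH at 15 min, and for mitochondrial and non-coding genes at 30 min. The glutamate-cysteine ligase gene gcs1, the first step of glutathione synthesis, was nonetheless higher at 15 min (0.37 ± 0.05), 30 min (0.59 ± 0.05) and with H2O2 (600 ± 13.2 against 340 ± 2.81 CPM, adjusted p = 3.37e-09). Without library b of the controls the proteasome list passed at 10 min (adjusted p = 3.63e-04), at 15 min (0.0192) and with H2O2 (3.14e-04). It also passed at 10 min without library a of plasma 10 min (0.0164) and with H2O2 without library c of H2O2 (0.0416).

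The time course compared the plasma samples with each other. From 10 to 15 min 400 genes were higher and 311 lower, from 15 to 30 min 785 and 713, and from 10 to 30 min 1035 and 986. With total counts in place of TMM scaling the share of higher genes moved from 56.3 to 70.8% from 10 to 15 min (371 higher, 153 lower), from 52.4 to 29.4% from 15 to 30 min (378 and 906), and from 51.2 to 40.7% from 10 to 30 min (712 and 1039). Without library a of plasma 10 min the genes changed from 10 to 15 min numbered 464. Pap1-regulated genes continued to rise, 12 of 16 higher and 1 lower from 10 to 15 min (13 and 1 adjusted over the list alone, adjusted p = 1.01e-10). From 10 to 30 min 15 of 16 were higher (15 adjusted over the list alone, adjusted p = 1.1e-09). Both calls were lost with an estimated correlation, at an adjusted p of 0.0945 and 0.186. Mitosis and cell separation genes fell in 18 of 25 cases from 10 to 15 min (20 lower and 1 higher adjusted over the list alone, adjusted p = 8.34e-16, and adjusted p = 0.0945 with an estimated correlation). Iron uptake was the list whose call also held with an estimated correlation, in 2 comparisons. It rose from 10 to 30 min, 13 of 20 genes higher and 2 lower (13 and 2 adjusted over the list alone, adjusted p = 7.29e-06, and adjusted p = 0.0186 with an estimated correlation). From 15 to 30 min 11 were higher (13 adjusted over the list alone, adjusted p = 4.85e-05, and adjusted p = 0.0322 with an estimated correlation). In that list str3 (SPAC1F8.03c), annotated as a siderophore transporter, went from 3.97 ± 1.11 CPM at 10 min to 33.6 ± 4.63 CPM at 30 min (3.07 ± 0.19, adjusted p = 1.39e-08).

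Single genes took different courses over time. pyp2 fell from 323 ± 30.4 CPM at 10 min to 70.2 ± 17.1 CPM at 30 min (-2.2 ± 0.25, adjusted p = 8.07e-06). cmt2 (SPBPB21E7.04c), a catechol methyltransferase, rose from 29.0 ± 3.15 to 175 ± 11.5 CPM over the same interval (2.6 ± 0.1, adjusted p = 2.8e-10), and the ammonium transporter gene amt1 (SPCPB1C11.01) from 44.4 ± 5.43 to 225 ± 26.5 CPM (2.35 ± 0.12, adjusted p = 3.03e-09). urg1 rose again from 22.2 ± 2.48 CPM at 15 min to 115 ± 8.56 CPM at 30 min (2.37 ± 0.19, adjusted p = 1.03e-06). The chaperone gene ssa1 was lower at 15 min than at 10 min, 355 ± 134 against 1160 ± 405 CPM (-1.71 ± 0.48, adjusted p = 0.0284), a call lost without library b of plasma 10 min (-1.37) or library a (-1.44) or c (-1.75) of plasma 15 min. Genes at least 2-fold higher than without irradiation at any plasma time numbered 450. Of these, 218 were higher at 30 than at 10 min, 50 were lower and 182 did not pass between these times. Genes 2-fold higher only at a later time are in this set, so it favours a rise after 10 min. From 15 to 30 min, proteasome genes rose in 16 of 34 cases (21 adjusted over the list alone, adjusted p = 1.14e-07). Ergosterol and hypoxia genes rose in 10 of 15, with 1 lower (12 and 1 adjusted over the list alone, adjusted p = 5.5e-06), and MBF genes in 9 of 18, with 1 lower (11 and 1 adjusted over the list alone, adjusted p = 0.00158). The adjusted p with an estimated correlation was 0.52 for the proteasome and MBF lists and 0.206 for ergosterol. Non-coding RNA genes moved down over that interval, 96 of 636 lower and 27 higher (84 and 25 adjusted over the list alone, median -0.21, adjusted p = 4.6e-04, and adjusted p = 0.52 with an estimated correlation).

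**Figure D4:**
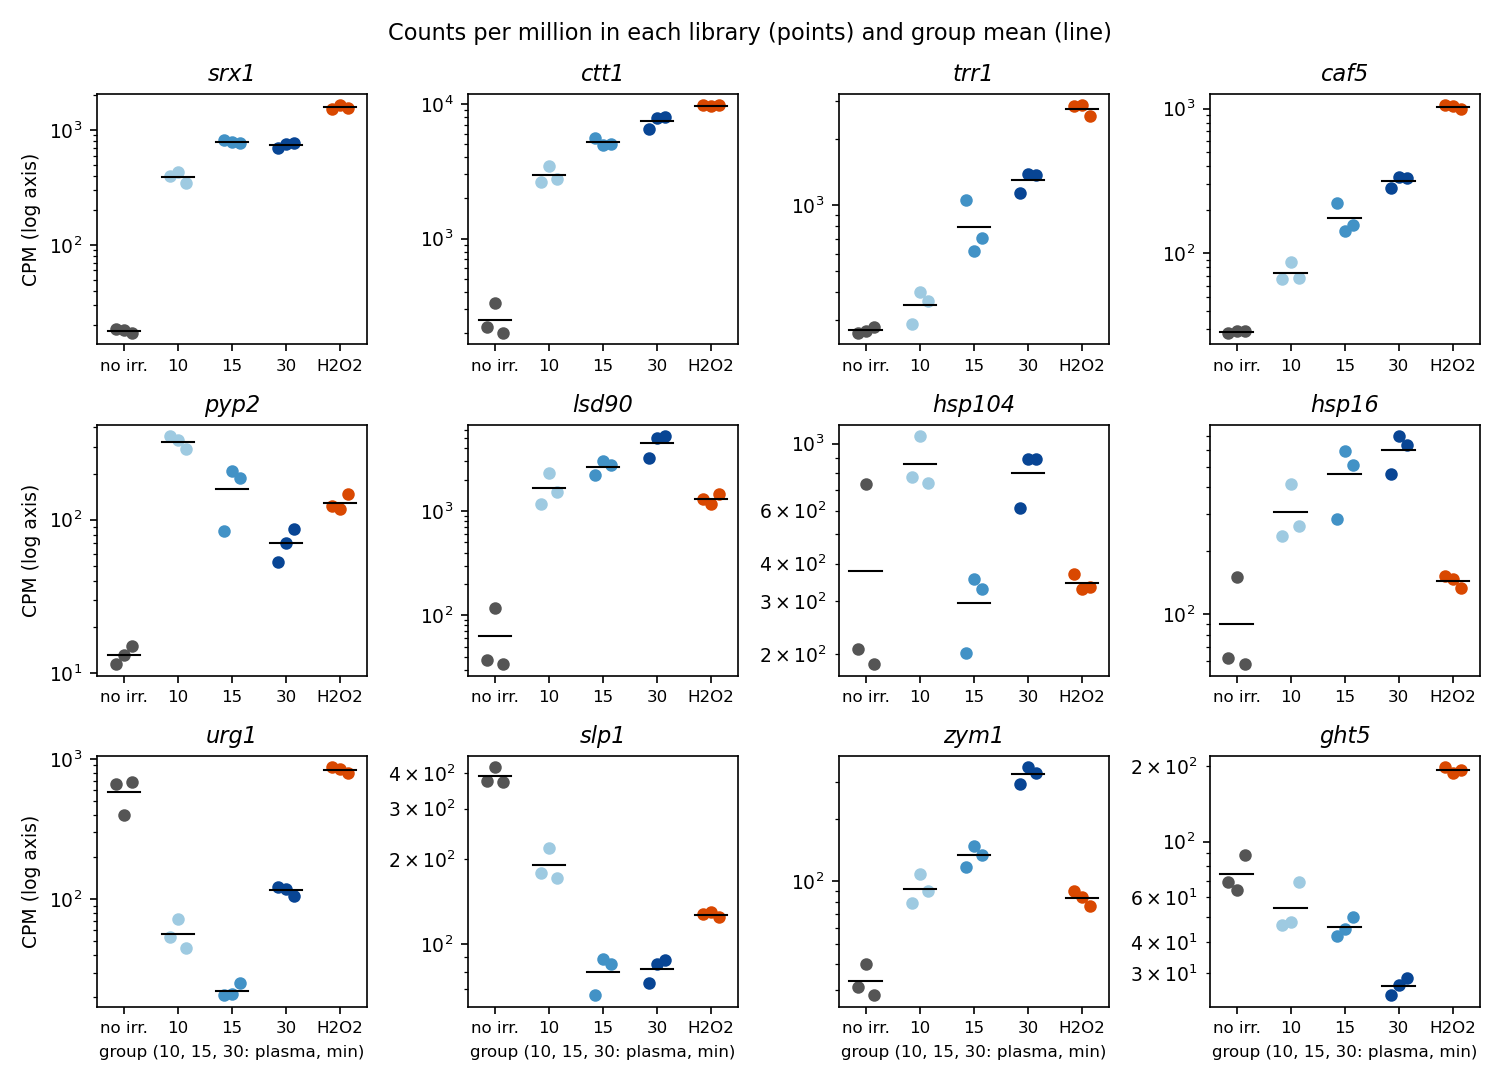
CPM (vertical log axis) of 12 genes in each library (points) and the group mean (line), for no irradiation, 10, 15 and 30 min after plasma, and H2O2 (horizontal axis, 3 libraries each). srx1 stood at 17.98 CPM without irradiation and 1590 CPM with H2O2, urg1 at 584 and 839 CPM, and at 22.2 CPM 15 min after plasma. The genes drawn were chosen after their values were seen.

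The last comparisons set plasma against H2O2. The times named are those of plasma, since the time of H2O2 and both doses are not given in the sources used here. Kind of treatment, dose and time therefore cannot be told apart in these differences. Both treatments raised 893 genes and lowered 575 at 10 min (352 lowered when fitted to the groups compared alone), 1099 and 930 at 15 min, and 1187 and 1051 at 30 min. Independent lists of these sizes would share 325.2 and 226.5, 402.4 and 331.8, and 460.6 and 386.9 genes, and part of the excess over these may come from the shared controls, which at 3 libraries cannot be split. In 20 simulated data sets of unchanged groups against the same controls 0 calls of edgeR were shared on average, a value that leaves out the effects and so is no reference for lists of these sizes. Across genes, which are not independent replicates, the covariance of the log2 fold changes was 0.237, 0.323 and 0.374 at the 3 times, above the simulated one by 0.223, 0.309 and 0.36. In all 4 treatments 818 genes were higher and 497 lower than without irradiation. Of the genes called in the same direction, 460 of 1468, 458 of 2029 and 771 of 2238 still differed in size between plasma and H2O2, and 84, 45 and 53 genes were called in opposite directions.

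Plasma and H2O2 differed in 1685 genes at 10 min (774 higher with plasma, 911 lower), 1203 at 15 min (516 and 687) and 1667 at 30 min (797 and 870). With total counts in place of TMM the share of genes higher with plasma moved from 42.9 to 52.7% at 15 min (444 higher, 398 lower), and from 47.8 to 36.6% at 30 min (481 and 834). Pap1-regulated genes were lower with plasma at each time, 14 of 16 at 10 min, with 1 higher (14 and 2 adjusted over the list alone, median -1.64, adjusted p = 2.43e-12). At 15 min 14 were lower, with 1 higher (14 and 1 adjusted over the list alone, adjusted p = 2.33e-10), and 9 at 30 min, with 1 higher (11 and 1 adjusted over the list alone, adjusted p = 8.25e-04). osr1 stood at 27.8 ± 1.83 CPM 10 min after plasma and at 594 ± 63.2 CPM with H2O2 (-4.42 ± 0.16, adjusted p = 4.44e-11). urg1 stood at 22.2 ± 2.48 CPM 15 min after plasma and at 839 ± 36 CPM with H2O2 (-5.23 ± 0.22, adjusted p = 2.15e-10). ght5 (SPCC1235.14), a high-affinity glucose transporter, stood at 26.7 ± 2.15 CPM 30 min after plasma and at 192 ± 4.9 CPM with H2O2 (-2.85 ± 0.14, adjusted p = 4.75e-09). The core stress list did not pass at 10 min (adjusted p = 0.828, with median and mean above 0 and the test below). It passed at 15 min, with 8 genes higher with plasma and 5 lower (12 and 5 adjusted over the list alone, adjusted p = 0.0281). That call was lost without library b (0.0909) or c (0.0751) of plasma 15 min or library c of H2O2 (0.0506). At 30 min 19 of 37 core stress genes were higher with plasma and 3 lower (21 and 4 adjusted over the list alone, median 0.59, adjusted p = 9.9e-06). The adjusted p with an estimated correlation was 0.0886, 0.253 and 0.626 for the Pap1 list, and for core stress 0.783 at 15 min and 0.853 at 30 min.

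Against no irradiation the heat shock list did not pass at 15 min (adjusted p = 0.429), at 30 min (0.161) or with H2O2 (0.239, median -0.20). Without library b of the controls it passed at 15 min (0.0257) and 30 min (0.00957). In the direct comparison heat shock genes were higher after plasma than with H2O2, 17 of 25 at 10 min, with 1 lower (17 and 1 adjusted over the list alone, median 0.67, adjusted p = 1.17e-04). At 15 min 9 were higher and 1 lower (11 and 1 adjusted over the list alone, adjusted p = 0.00476), and 16 at 30 min, with 2 lower (17 and 3 adjusted over the list alone, adjusted p = 5.89e-04). hsp16 stood at 600 ± 123 CPM 30 min after plasma against 144.1 CPM with H2O2 (adjusted p = 3.61e-04), and ssa1 at 1150 ± 366 against 283 ± 15.1 CPM (2.02 ± 0.49, adjusted p = 0.00539). Histone genes were also higher, 6, 7 and 7 of 8 at the 3 times (7, 8 and 8 adjusted over the list alone, adjusted p = 0.00311, 1.8e-05 and 1.52e-05). So were nuclear oxidative phosphorylation genes, 21, 21 and 27 of 41, with 2, 2 and 1 lower (24, 23 and 27 higher and 2, 2 and 2 lower adjusted over the list alone, adjusted p = 1.24e-05, 3.02e-08 and 2.22e-08). Alternative carbon genes were lower with plasma, 11, 9 and 9 of 16, with 1, 2 and 1 higher (12, 11 and 9 lower and 1, 2 and 1 higher adjusted over the list alone, adjusted p = 6.37e-05, 2.83e-04 and 0.00926). The call at 30 min was lost without library a of plasma 30 min (adjusted p = 0.0669). The adjusted p with an estimated correlation at the 3 times was 0.448, 0.598 and 0.853 for heat shock and 0.448, 0.259 and 0.626 for histones. It was 0.407, 0.259 and 0.626 for oxidative phosphorylation, and 0.173, 0.253 and 0.626 for alternative carbon use.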

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

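The 3 tests of the heat shock values of 1 control library and the tests of RNA carry-over behind the mitochondrial values were chosen only after the result was seen. The counts in the next paragraph were singled out because the effects of 2 treatments or times against the same controls differed by a test of the difference itself in edgeR or camera. The heat shock and mitochondrial patterns weighed after them were not chosen by that rule.

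Between plasma times, 711 genes changed from 10 to 15 min, 1498 from 15 to 30 min and 2021 from 10 to 30 min, with 10, 12 and 14 of the 26 gene lists passing and 8, 10 and 12 of the 19 measured panel genes changed. Between plasma and H2O2, 1685, 1203 and 1667 genes differed at 10, 15 and 30 min, with 14, 15 and 9 lists passing and 11, 10 and 12 panel genes changed. These list counts hold with the preset correlation. With an estimated one iron uptake alone passed, from 15 to 30 min and from 10 to 30 min. Genes called in opposite directions against no irradiation, with no minimum fold change, numbered 84 at 10 min, 45 at 15 min and 53 at 30 min.

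Heat shock transcripts stood high in library b without irradiation, with hsp104 at 737 CPM against 209 and 185 CPM in libraries a and c, and ssa1 at 763 against 182 and 168 CPM. A treated library under the wrong label is argued against by srx1, which stood at 18.1 CPM in library b where the lowest treated library held 344 CPM. Scaling set by a few abundant genes is argued against by the difference of 0.57 (95% bootstrap interval 0.17 to 1.23) between the medians of the heat shock list, 0.59, and the Pap1 list, 0.02, in that library, which no factor common to all genes can change. The interval comes from resampling genes, which may vary together, within that library, and holds no spread between libraries. A general stress of that culture before harvest stays open as a hypothesis, since core stress genes outside the heat shock list had a median log2 difference of 0.43 between that library and the mean of the other two. The design names no difference between the 3 control cultures, so no biological explanation beyond this one was tested.

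Mitochondrially encoded genes were lower at 15 min after plasma by a median log2 fold change of -1.95 (median SE 0.64), and at 10 min, where the list passed only with the library letter as a block, by -1.05. Carry-over of RNA outside the mRNA selection stays open as a candidate explanation, since within groups the log2 shares of mitochondrial and ribosomal RNA genes went together over the 15 libraries (Pearson r = 0.967, Spearman rho = 0.95, exact permutation p = 0.000129 for both, the smallest that 7776 orders can give). Without library c of the controls and library c of plasma 30 min r was 0.955. The permutation p treats the groups as independent. Both shares fell from letter a to c in each of the 5 groups. If letters mark a shared preparation, this p is therefore no measure of an association beyond the letter. With the ribosomal RNA share as a covariate the median became -0.21 (median SE 0.24) and the lower calls went from 7 to 0 in edgeR, because the fold shrank and not because its error grew, while the calls over all genes went from 1412 higher and 1295 lower to 1118 and 853. Genes annotated as ribosomal RNA were counted in the ribosomal RNA share whatever their chromosome, so that share can hold mitochondrial ribosomal RNA. A fall of mitochondrial RNA in the cells could then move both shares together, so these values cannot tell it from carry-over. An effect of plasma on mitochondrial transcripts was not tested apart from this share and also stays open.

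Non-coding RNA genes were lower at 30 min than at 15 min by a median of -0.212. Reads of overlapping coding genes, counted without strand, are argued against by the 207 non-coding genes that overlap no coding gene, with a median of -0.302 (95% bootstrap interval -0.407 to -0.207) against -0.167 for the 429 that overlap one. The intervals in this paragraph come from resampling genes, which may vary together, and not libraries. A shift of weakly expressed genes in general stays open as a candidate explanation, since 636 draws of coding genes matched on mean expression, 384 of them distinct, had a median of -0.173 (-0.236 to -0.119 with all draws of a gene resampled together). The time after irradiation also stays open as a biological explanation, which was not tested apart from this shift.

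For 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In each comparison 1 split, the real one, gave as many genes. Each other split puts libraries of both groups on each side. A difference between the groups then widens the spread within sides, so few calls there are no measure of what chance gives. In fits to the groups compared alone the real split gave 890 genes higher and 546 lower at 10 min, 1251 and 1035 at 15 min, 1437 and 1388 at 30 min, and 1334 and 1143 with H2O2, and the highest of the other splits gave 0 in edgeR. Between plasma times the real split gave 683 genes from 10 to 15 min (highest other 1), 1746 from 15 to 30 min (0) and 2124 from 10 to 30 min (0). Between plasma and H2O2 it gave 1724 at 10 min (0), 1408 at 15 min (0) and 2013 at 30 min (4).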

How the results depend on the processing

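The library letter as a block and the lists without members matched by name alone were not among the alternatives chosen at first. No paired analysis was possible because the columns carry letters and not the replicate numbers of the labels. The letter was fitted as a block in its place. Across genes, the deviations of libraries of 1 letter from their group means correlated by 0.206 to 0.31 between no irradiation and plasma 10 min and by 0.124 to 0.227 between plasma 10 and 30 min, a hint from the data that letters may mark a shared preparation. In each other pair of groups at least 1 letter was under 0.1 (lowest -0.113). With the letter as a block 1163 genes were higher and 930 lower at 10 min, and 2117 changed from 10 to 30 min. Of the list results, 250 kept their side of the threshold, 8 came to pass, among them mitochondrial genes at 10 min (0.013) and from 10 to 30 min (0.0217), and 2 no longer passed, MBF genes at 15 min (0.0505) and NADPH supply against H2O2 at 10 min (0.05). Without members matched by name alone 252 list results kept their side, 5 came to pass and 3 no longer passed. The 20 counts compared are genes higher and lower per treatment, genes changed in both directions together between times or between plasma and H2O2, and genes higher or lower both with plasma and with H2O2. These stayed within 1.5 times with the letter block, RLE size factors, total counts, DESeq2, either change of the low-count filter, and without non-coding, Tf2 and mitochondrial genes. Split by direction, total counts moved some further, such as 785 to 378 genes higher from 15 to 30 min and 311 to 153 lower from 10 to 15 min. A minimum of 2-fold, which asks for more than the test alone, left 240 genes higher and 35 lower at 10 min, 306 and 82 at 15 min, 356 and 111 at 30 min, and 343 and 65 with H2O2. It left 72, 104 and 192 genes between plasma times 10 and 15, 15 and 30, and 10 and 30 min, and 251, 146 and 135 between plasma and H2O2 at 10, 15 and 30 min. Of the genes shared with H2O2 it left 172 higher and 9 lower, 225 and 27, and 237 and 35 at the 3 times. Fitted to the groups compared alone, with fewer libraries to estimate the spread, 546 genes were lower at 10 min and 352 were lower both at 10 min and with H2O2. Genes changed from 10 to 15 min ranged from 464 without library a to 648 without library b of plasma 10 min when 1 library was left out. The other 101 counts with 1 library left out stayed within 1.5 times.

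With an estimated correlation 0 lists passed in 8 comparisons, and 1 list, iron uptake, passed from 15 to 30 min and 1, the same list, from 10 to 30 min. With the preset correlation and 1 library left out, 1458 list results kept their side of the threshold, 55 came to pass, 46 no longer passed and 1 reversed. That was the ribosomal protein list from 10 to 15 min, with an adjusted p of 3.84e-13 without library a and 0.829, in the other direction, without library c of plasma 10 min. The cause was not tested. For single genes 1654 results kept their call, 5 came to pass, 49 no longer passed and 2 reversed. Both were hsp104, at -0.68 to 0.59 at 15 min and -0.45 to 0.81 with H2O2, positive without library b of the controls, in which hsp104 was highest. Without that library 1128 genes were higher and 930 lower at 10 min, 1424 and 1170 at 15 min, 1667 and 1364 at 30 min, and 1469 and 1159 with H2O2. Summed over genes, the spread between replicate libraries exceeded counting error, but no test with fewer reads was run. With 3 libraries per group changes under 1.5-fold were not tried in the simulated data. Against no irradiation, the genes called had a median absolute log2 fold change of 0.366, 0.382 and 0.45 at the 3 plasma times. With H2O2 it was 0.39. These medians lie under 1.5-fold, so the simulated recovery does not cover most of these calls.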

Other observations

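Genes called in opposite directions by plasma at 10 min and by H2O2 are given here as single genes, chosen after their values were seen. The uricase gene uro1 (SPCC1223.09), an enzyme of purine breakdown, was lower at 10 min after plasma and higher with H2O2, by log2 fold changes of -0.66 and 1.72 (difference -2.38 ± 0.12 SE, adjusted p = 7.08e-10). The amino acid transporter gene isp5 (SPAC1039.09) stood at -1.06 and 0.52 (difference -1.58 ± 0.11), and isp7 (SPAC25B8.13c), an oxygenase gene, at -1.08 and 0.9 (difference -1.98 ± 0.13). The alcohol dehydrogenase gene adh4 (SPAC5H10.06c) stood at -0.68 and 0.93, and the transporter gene mfs1 (SPAC17C9.16c) went the other way, at 1.2 and -0.58 (difference 1.79 ± 0.09, adjusted p = 8.79e-10). The sterol desaturase gene erg31 stood at -0.49 and 0.96, and the coproporphyrinogen oxidase gene hem13 (SPAC222.11) at -0.41 and 0.74.

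Several genes outside the lists rose between plasma times. ecl1 (SPCC70.12c), named for its part in chronological lifespan, rose from 34.7 CPM at 10 min to 171 CPM at 30 min (log2 fold change 2.3 ± 0.13), and SPAC186.06, an isomerase gene, from 4.63 ± 0.686 to 45.7 ± 9.23 CPM (3.31 ± 0.16, adjusted p = 1.51e-09). Between plasma at 30 min and H2O2, the kinase gene ppk8 stood at 93.7 and 419 CPM (-2.16 ± 0.07, adjusted p = 6.95e-11), and the F-box gene pof15 at 36.7 and 5.16 CPM (2.83 ± 0.21, adjusted p = 1.49e-07). Genes at least 2-fold lower than without irradiation at any plasma time numbered 160. Of these, 85 were lower at 30 than at 10 min, 18 were higher and 57 did not pass between these times. Genes 2-fold lower only at a later time are in this set, so it favours a fall after 10 min.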
